A study of Rattus norvegicus with 4 samples.

How the data were processed

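The series measured RNA levels in NR8383 cells, a rat alveolar macrophage line that was set up from the lung lavage of a normal rat. All 4 samples carry the same label, a water control of 4 h with the added tag ALI, which the labels do not spell out. Per the labels, the cells had gone through 20 passages, had been seeded for 48 h in flasks of 25 cm2, and gave RNA with an integrity number above 7.5. The series design text calls the 4 samples biological replicates. The series holds 1 group, so no comparison between conditions was made, and other conditions were not analysed here.

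Per the labels' protocols, 100 ng of RNA per sample was copied into cRNA labelled with the dye Cy3 and hybridised to a one-colour Agilent rat array. Per the file headers, each deposited file is the output of 1 array from Agilent Feature Extraction 11.0.1.1, and all 4 arrays lie on 1 slide with 1 scan date. Per the file headers, the values are spot intensities on a linear scale: the processed signal after Feature Extraction's own background handling, the median signal and the local background. The deposited files also hold, per the file headers, flags of another kind (0 or 1) that say whether a spot was well above background, positive and significant, saturated, or an outlier. No step between arrays had been applied to the deposited intensities. The submitters' processing notes name no further tool.

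Each array held 58717 spots of gene probes, which belong to 45598 probes, and 308 negative control spots. Control spots were left out of all gene results. Spots of 1 probe were averaged on the log2 scale, leaving out spots with an outlier flag, which made up 1.11% to 1.45% of the spots. No spot was saturated. The main value was the log2 of the processed signal minus the 75th percentile of the array, so 0 stands for the 75th percentile. The 75th percentile was an intensity of 878, 932, 1237 and 831 on replicates 1 to 4. Probes differ in affinity, so a value serves to follow 1 probe across the arrays and not to rank genes.

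The files used here pair spots with accessions and not with gene names. Accessions were matched without versions to the RefSeq gene table of the assembly GRCr8, which served for names only; the array's header names another build (rn4), so no coordinates are given. Of the 45598 probes, 21109 (46.3%) matched 1 gene and 0 matched several, giving 16581 named genes. The other 24489 probes are unnamed here, 6958 of them with Ensembl accessions and 13212 with predicted RefSeq accessions. Some genes of the lists therefore had no named probe. For the 3658 genes with more than 1 probe, the value was that of the probe with the highest mean. The probes of 721 of these genes differed in detection. A gene with 1 named probe, such as Gclm, Hk1 or Ahr, could thus be called not detected because of that probe alone.

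A gene was called detected when at least 1 of its probes was well above background on 4 of 4 arrays. It was called not detected when no probe was well above background on any array, and partly detected otherwise. A probe with several spots counted when more than 50% of its spots without an outlier flag did. A probe with no such spot on an array counted as not above background there, and 65 probes had none on some array. Detection of each of 34 gene lists was set against all other named genes with a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the lists. Genes are not independent, so these p-values describe the lists. The lists were macrophage, alveolar macrophage, alveolar type 1, alveolar type 2, airway epithelium, endothelium, fibroblast, T cell, B cell, NK cell, neutrophil, mast cell and basophil, dendritic cell, erythroid, inflammatory cytokines and chemokines, alternative activation, pattern recognition receptors and inflammasome, phagocytic and scavenger receptors, MHC class II presentation, interferon response, Nrf2 antioxidant, metal response, aryl hydrocarbon and xenobiotic response, hypoxia and glycolysis, heat shock, unfolded protein response, p53 and DNA damage, proliferation, immediate early genes, osmotic response, lysosome, cholesterol and lipid handling, matrix proteases and inhibitors, and X and Y sex-linked genes.

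Variation between the 4 arrays was tested for 8453 detected genes with limma 3.58.1 in R 4.3.3. A model with an intercept only was fitted, and the residual variance of each gene was set against the variance that eBayes fitted for genes of the same signal (with trend and robust fitting) in an upper-tail F test, adjusted by Benjamini-Hochberg at a threshold of 0.05. Genes past that threshold are called hypervariable. For lists with at least 5 detected members, the median SD of the members and the SD of the list mean over the arrays were given as percentiles among 10000 random lists of the same size, matched on mean signal in 20 bins. These percentiles are descriptions with no p. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

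The variance test was tested on simulated data for the comparison of 4 arrays, with 8456 genes and 200 of them given a larger SD. Each simulated SD was drawn around the fitted one. The test recovered 0% of genes whose drawn SD was multiplied by 2, 24.5% at 4 times and 77.0% at 8 times. False calls numbered 0, 0 and 2, and 0 calls were made when no gene was changed. The simulated noise was independent between genes and arrays, so false calls from shifts shared by many genes on 1 array were not covered. The percentile of a list mean was tested on 6000 simulated genes: a list of 20 genes shifted by 0.3 (log2) on 1 array reached percentile 100, and 3 of 50 unshifted lists passed percentile 95. Here too the noise was independent between genes, so the share of such lists passing was not checked for genes that share shifts. The number of arrays, 4, limits the precision of every value.

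Named in the text are, by a rule fixed before the data were examined, the key members of each list, some of which are not reported here; the exceptions of a list that was mostly detected or mostly not detected, where they numbered 5 or fewer; the 10 genes with the smallest p in the variance test; and any hypervariable or fully saturated member of a list. Probes of a named gene that differed in detection are stated. Any other gene named was chosen after its values were seen.

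The alternatives fixed before the data were examined changed 1 choice at a time, apart from normexp, which also changed the signal column. For detection these were the 95th percentile of the negative controls, the positive and significant flag, 3 of 4 arrays, the brightest probe only and, for the number of detected genes, a limma test against the negative controls. For variation these were quantile normalization, no scaling, the 75th percentile over detected probes, normexp background correction with an offset of 50, no filter on dim probes, the first probe by name, and the fit without trend, without robust fitting or at an adjusted p of 0.01. Each array was also left out in turn. Normexp had been planned on the mean signal and was run on the median signal instead, the foreground column used here, so it replaced the processed signal as well as the background correction. A block for the slide was not applicable, since all arrays share 1 slide. Cyclic loess normalization and the removal of probes with a single far brighter array were chosen after the data were seen, as was the metal response list without Mt1 and Mt2A.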

Results

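RNA of NR8383 rat alveolar macrophages kept for 4 h in the water control condition was measured on 4 one-colour arrays, 1 per biological replicate. The labels state the purpose only as recording gene expression in this control condition. Between 49.2% and 50.3% of the gene spots were well above background on each array. Across pairs of arrays, Pearson's r over 17324 detected probes lay between 0.990 and 0.994; this r is across probes, which are not independent replicates. Between 1.70% and 2.19% of raw values were identical between any pair of arrays, so all 4 arrays were kept as separate samples. Values below are log2 signals relative to the 75th percentile of the array, as mean ± SD (n = 4 arrays).

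Most markers of macrophages, and of alveolar macrophages, were detected in these cells. Of the 20 macrophage markers, 16 were detected, among them Cd68, a lysosomal glycoprotein of macrophages (5.07 ± 0.26), Csf1r, the receptor for the growth factor CSF1 (-0.97 ± 0.17), Spi1, the macrophage lineage transcription factor PU.1 (1.14 ± 0.10), Mrc1, the mannose receptor (0.32 ± 0.16), and Adgre1, the F4/80 antigen (-3.96 ± 0.23). The 4 exceptions were the scavenger receptor Cd163 and the complement genes C1qa, C1qb and C1qc, none of which was well above background on any array. Of 17 alveolar macrophage markers with a named probe, 13 were detected, including Pparg, the nuclear receptor of alveolar macrophage differentiation (4.10 ± 0.17), and Fabp4, a fatty acid binding protein (1.32 ± 0.18). Marco, a scavenger receptor, Car4, a carbonic anhydrase, and Fabp1 were not detected, and Rnase17 was well above background on 2 arrays. The key genes Itgax and Bhlhe41 had no named probe. Among all 16581 named genes, 8456 (51.0%) were detected, 1066 partly and 7059 not; the named genes include 1106 olfactory receptor genes, of which 23 were detected. Against that background the macrophage list was detected more often (adjusted p = 0.0374, Fisher's exact test), and the alveolar macrophage list did not pass the test (adjusted p = 0.0938). Over the 8 alternatives the adjusted p of the macrophage list ranged from 0.0373 to 0.0773, the latter with detection set by the negative controls.

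Markers of other lung and blood cells were mostly not well above background. Across the 12 lists of such cells, 23 of 108 genes were detected, 6 partly and 79 not. None of the 8 alveolar type 1 markers was detected (adjusted p = 0.0148, Fisher's exact test), with Ager and Aqp5 not well above background on any array and Hopx above it on 1. Of 10 fibroblast markers only Dcn, a small matrix proteoglycan, was detected (0.10 ± 0.24), while Col1a1 and Pdgfra were not (adjusted p = 0.0349). Of 9 mast cell and basophil markers only Hdc, the histamine-forming enzyme, was detected (-4.63 ± 0.36, by 1 of its 2 probes), and Cpa3 and Ms4a2 were not (adjusted p = 0.0476). Over the 8 alternatives, the adjusted p ranged from 0.0105 to 0.105 for alveolar type 1, from 0.00738 to 0.0350 for fibroblast and from 0.0471 to 0.389 for mast cell and basophil. The first and the last lost their call with the negative controls and with the positive and significant flag.

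The other 9 of these lists did not pass the test. Of the alveolar type 2 markers, 3 of 9 were detected (Napsa 3.54 ± 0.13, Etv5 1.78 ± 0.03, Lpcat1 -3.82 ± 0.33), and the surfactant genes Sftpc and Sftpb and the phosphate transporter Slc34a2 were not (adjusted p = 0.392). Foxj1, the regulator of motile cilia, was the 1 detected gene of 8 in the airway epithelium list (-3.98 ± 0.39, by 1 of 2 probes), without Scgb1a1 or Epcam (adjusted p = 0.0711). Of 10 endothelial markers, Pecam1 (-1.04 ± 0.12), Cdh5 (-4.52 ± 0.63) and Vwf (1.27 ± 0.28, by 1 of 2 probes) were detected and Kdr was not (adjusted p = 0.296). Of 12 T cell markers, Cd4 (-5.06 ± 0.45, by 1 of 2 probes), Cd28 (0.72 ± 0.29, by 1 of 2 probes) and Lck (-3.68 ± 0.08) were detected, while Cd3e and Cd3g were not (adjusted p = 0.140). Of 8 B cell markers, Pax5 (-2.17 ± 0.14) and Fcrla (1.13 ± 0.08) were detected (adjusted p = 0.243); Cd79a had no named probe. Of 9 NK cell markers, Gzmb (-3.12 ± 0.25, by 1 of 2 probes), Nkg7 (-4.54 ± 0.33) and Tbx21 (2.79 ± 0.26) were detected and Ncr1 was not (adjusted p = 0.392). Of 10 neutrophil markers, Camp (-0.26 ± 0.23) and Lcn2 (3.70 ± 0.41) were detected, and S100a8, S100a9 and Csf3r were not (adjusted p = 0.103). In the dendritic cell list Batf3 was detected (-2.83 ± 0.25) among 8 genes, and Zbtb46 and Fscn1 were not (adjusted p = 0.0711). Clec9a counted as partly detected. Its brightest probe was above background on replicates 1 and 4 (-2.42 and -2.81) and had no spot without an outlier flag on replicates 2 and 3. Of 7 erythroid markers, Hba-a1 (-1.92 ± 0.41), Epor (-4.27 ± 0.22) and Klf1 (-4.14 ± 0.20) were detected, and Hbb and Alas2 were not (adjusted p = 0.766). With the positive and significant flag the airway epithelium list (adjusted p = 0.0269, range over the 8 alternatives 0.0269 to 0.103) and the neutrophil list (0.0468, range 0.0468 to 0.103) passed the test, and with the negative controls the dendritic cell list did (0.0285, range 0.0285 to 0.105).

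Among the immune function lists, sensing and interferon genes were detected more often than other genes, and 8 of 12 MHC class II genes were not detected. Of 19 pattern recognition and inflammasome genes, 15 were detected (adjusted p = 0.0476, Fisher's exact test), including the bacterial sensors Tlr2 (2.82 ± 0.08) and Tlr4 (-0.31 ± 0.20), the beta-glucan receptor Clec7a (4.18 ± 0.02), and the inflammasome genes Nlrp3 (0.26 ± 0.22) and Casp1 (-0.32 ± 0.11); Tlr1 and Tlr9 were not, and Tlr5 and Tlr10 were above background on 1 array each. Of 19 interferon response genes, 16 were detected (adjusted p = 0.0172), among them Isg15 (0.01 ± 0.21), Mx1 (-0.52 ± 0.12) and the transcription factor Irf7 (0.75 ± 0.30). The interferon gene Ifnb1 and Ifit1 were not detected, and Ifih1 was well above background on 3 arrays. Of 12 MHC class II genes, 4 were detected (adjusted p = 0.333), namely Ctss (2.01 ± 0.02), RT1-DMa (1.53 ± 0.20), RT1-DMb (2.02 ± 0.29) and RT1-Db1 (-4.06 ± 0.51). The class II chain RT1-Da, the invariant chain Cd74, the class II regulator Ciita and the costimulatory gene Cd86 were not. Over the 8 alternatives, 4 to 7 of the 12 genes were detected, and the list never passed the test. The adjusted p of the pattern recognition list ranged from 0.00738 to 0.0568 over the 8 alternatives, the latter with detection on at least 3 of 4 arrays.

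Of 25 inflammatory cytokine and chemokine genes, 15 were detected (adjusted p = 0.483). The cytokines Tnf (2.67 ± 0.29) and Il1b (4.46 ± 0.12) and the chemokines Ccl2 (5.66 ± 0.27), Ccl3 (5.79 ± 0.25) and Cxcl2 (0.81 ± 0.42) were detected, as was Nos2, the inducible nitric oxide synthase (-3.72 ± 0.22, by 1 of 2 probes). Il6 and Ptgs2, the inducible prostaglandin synthase, were not well above background on any array. Of 14 alternative activation genes, 7 were detected (adjusted p = 1), with Arg1, the arginase of alternatively activated macrophages (2.06 ± 0.08), Il4r (-3.33 ± 0.17) and Tgfb1 (0.69 ± 0.18) detected and Retnla not. Of 18 phagocytic and scavenger receptors, 14 were detected (adjusted p = 0.0711), including Cd36 (4.58 ± 0.35), Msr1 (-0.44 ± 0.16), the Fc receptor Fcgr2b (1.87 ± 0.14) and Mertk, a receptor for dying cells (-2.50 ± 0.18). Cd163, Marco and Stab2 were not detected, and Scara5 was above background on 1 array. With the positive and significant flag the phagocytic list passed the test (adjusted p = 0.0400, range over the 8 alternatives 0.0400 to 0.101), as did the alveolar macrophage list (0.0491, range 0.0491 to 0.128).

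Of the 11 lists that were detected more often than other genes, 6 were stress response or growth lists. Gene families that nearly every cell uses were detected to 96.8%, against 51.0% of all named genes. Passing this test thus does not make a list particular to these cells or to the water control. All 16 proliferation genes with a named probe were detected (adjusted p = 0.00108, Fisher's exact test), among them the cell cycle genes Mki67 (1.93 ± 0.17), Ccnb1 (0.24 ± 0.13) and Pcna (1.66 ± 0.08); Top2a had no named probe. Of 18 unfolded protein response genes, 17 were detected (adjusted p = 0.00128), including the chaperone Hspa5 (4.52 ± 0.15), the transcription factors Atf4 (4.47 ± 0.17) and Ddit3 (2.81 ± 0.16), Trib3 (1.42 ± 0.13) and Chac1 (-2.01 ± 0.22); Ern1 was above background on 2 arrays. Of 22 Nrf2 antioxidant genes, 20 were detected (adjusted p = 0.00128), including the haem oxygenase Hmox1 (4.57 ± 0.19), the quinone reductase Nqo1 (-2.24 ± 0.16), Srxn1 (3.59 ± 0.16) and the cystine transporter Slc7a11 (2.97 ± 0.12), while Gclm and Gpx2 were not. Of 13 heat shock genes, 12 were detected (adjusted p = 0.0148), with Hspa8 at 6.25 ± 0.38, Hsph1 at -3.19 ± 0.20 and the inducible Hspa1a at -2.83 ± 0.65 by 1 of 2 probes. Hspb1 was above background on 3 arrays, and Dnajb1 had no named probe.

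The p53 and DNA damage list had 15 of 17 genes detected (adjusted p = 0.0137, Fisher's exact test), with the cell cycle inhibitor Cdkn1a at 4.39 ± 0.14, Mdm2 at -0.07 ± 0.09, Gadd45a at 0.12 ± 0.15 and Ccng1 at 2.42 ± 0.06; Btg2 and Pmaip1 were not detected. The hypoxia and glycolysis list had 17 of 22 detected (adjusted p = 0.0476), with Hif1a at 1.71 ± 0.14, the glucose transporter Slc2a1 at 3.21 ± 0.11, Ldha at 6.55 ± 0.17 and Bnip3 at 0.12 ± 0.17. The growth factor Vegfa, Slc2a3, Hk1 and Egln3 were not detected, Vegfa by none of its 3 probes, and Car9 was above background on 2 arrays. Over the 8 alternatives the adjusted p ranged from 0.0105 to 0.0657 for the p53 list, the latter with the negative controls. For the hypoxia list it ranged from 0.0457 to 0.0913 and missed the threshold with the positive and significant flag and with at least 3 of 4 arrays.

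Lysosomal and lipid genes were also detected more often. Of 19 lysosome genes, 18 were detected (adjusted p = 0.00128, Fisher's exact test), with the cathepsins Ctsb (6.82 ± 0.30) and Ctsd (6.70 ± 0.39) and the membrane protein Lamp1 (3.25 ± 0.09); Ctsk was not. Of 20 cholesterol and lipid genes, 18 were detected (adjusted p = 0.00285), with the cholesterol exporter Abca1 (-2.92 ± 0.18), the lipid droplet protein Plin2 (3.81 ± 0.11) and Apoe (-4.20 ± 0.21). The fatty acid genes Fasn and Scd were not detected.

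The other lists did not pass the test. Of 12 metal response genes, 9 were detected (adjusted p = 0.217), with the metallothioneins Mt1 (3.99 ± 0.52) and Mt2A (0.77 ± 0.58) and the zinc exporter Slc30a1 (-0.33 ± 0.10); the iron exporter Slc40a1 was above background on 1 array, and Hamp and Mt3 on none. Of 11 genes of the aryl hydrocarbon list, 3 were detected (adjusted p = 0.214), namely Nqo1, Ugt1a6 (2.82 ± 0.05) and Arnt (-2.92 ± 0.27, by 1 of 2 probes); the receptor Ahr and its targets Cyp1a1 and Cyp1b1 were not, and Tiparp had no named probe. Of 20 immediate early genes, 13 were detected (adjusted p = 0.333), with Jun at 2.31 ± 0.35, Atf3 at 1.62 ± 0.21 and Egr1 at -4.51 ± 0.31, and Fos and Zfp36 were not; this list passed the test with the positive and significant flag (adjusted p = 0.0204, range over the 8 alternatives 0.0204 to 0.345). Of 14 osmotic response genes, 11 were detected (adjusted p = 0.103), with the taurine transporter Slc6a6 (4.12 ± 0.16), the transcription factor Nfat5 (-0.75 ± 0.05, by 1 of 2 probes), Slc5a3 (-3.95 ± 0.28), Akr1b1 (-0.20 ± 0.15) and the water channel Aqp1 (-4.92 ± 0.17, by 1 of 2 probes); Aqp3, Aqp9 and Slc12a2 were not. Of 17 matrix proteases and inhibitors, 10 were detected (adjusted p = 0.691), with Mmp9 (0.34 ± 0.17), Mmp12, the macrophage elastase (1.48 ± 0.45), Mmp14 (-3.81 ± 0.12), Timp1 (-3.90 ± 0.28) and Plaur (-2.01 ± 0.42). Of 3 sex-linked genes with a named probe, the Y-linked Ddx3y (-2.97 ± 0.24) and Eif2s3y (-3.50 ± 0.18) were detected and Uty was not (adjusted p = 1). In all, 11 of 34 lists were detected more often than other genes, 3 less often, and 20 passed in neither direction.

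**Figure D1:**
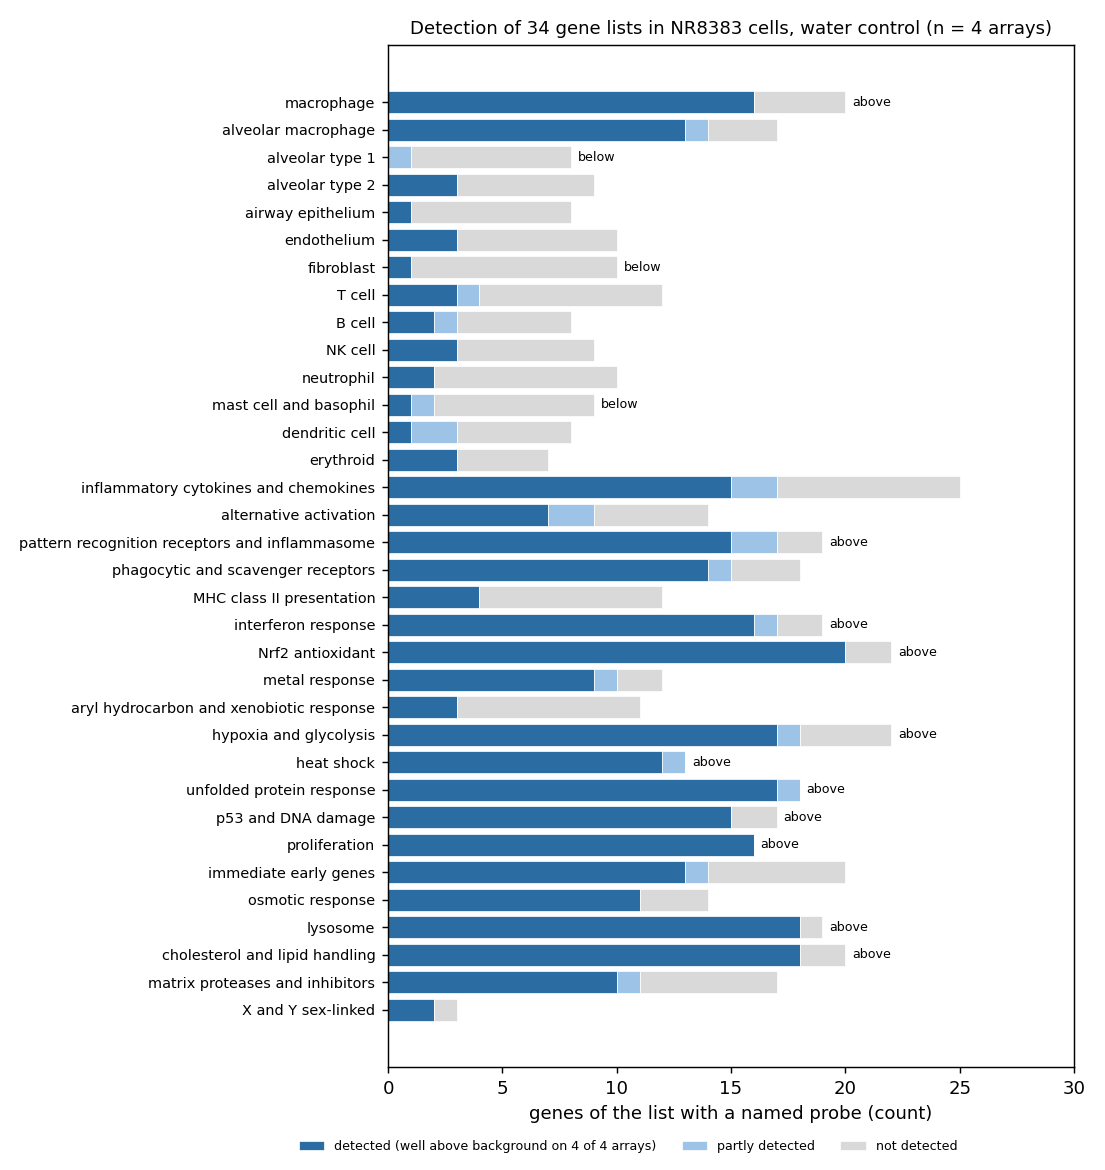
Number of genes per list (x axis, counts) that were detected, partly detected or not detected on the 4 arrays, 1 bar per list. The words above and below mark the 11 lists detected more often and the 3 detected less often than other named genes (Fisher's exact test, adjusted over 34 lists).

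Most transcripts differed little between the 4 replicates. The median SD between arrays was 0.144 on the log2 scale over the 8453 tested genes, and 275 genes spanned more than 2-fold between their highest and lowest array. Of the 289 tested genes in the fixed lists, 9 spanned more than 2-fold. These were Bax, Cdh5, Cxcl1, Hspa1a, Il23a, Mt1, Mt2A, Osgin1 and RT1-Db1, of which Bax, Cxcl1, Il23a and Osgin1 were chosen after their values were seen. None of the 289 was hypervariable by the limma variance test over all genes, and none was when p was adjusted over the list alone (35 had an unadjusted p under 0.05, and the fit without trend also called 0). Mt2A had the smallest adjusted p among them over all genes (0.0894, limma), and Mt2A, Mt1 and Bax shared the smallest over the list alone (0.0751). The count of genes over 2-fold was 127 without replicate 3, 162 without replicate 4, 832 with no scaling, 81 with normexp on the median signal and 3909 with no filter on dim probes. The median SD was 0.267 with no scaling and 0.219 with no filter.

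In the limma variance test 20 genes were hypervariable, and 5 of them stood far above on 1 array. Art3, a gene of the ADP-ribosyltransferase family, was at 7.18 on replicate 3 and between -3.32 and -3.13 on the others (adjusted p = 1.2e-07, limma). Ugcg, the glucosylceramide synthase, was at 8.69 on replicate 4, which was 8.93 above the median of the others (adjusted p = 1.2e-07, limma). Zfr, a zinc finger RNA-binding protein, was 8.51 higher on replicate 1 (adjusted p = 1.2e-07, limma). Alg5, a glycosylation enzyme, was 7.52 higher on replicate 3 (adjusted p = 2.6e-07, limma), and Zfand3 was 5.22 higher on replicate 4 (adjusted p = 3.0e-06, limma). Each of these 5 genes had 1 named probe. Except for Zfr, each lay within 3 rows and 3 columns of another spot that was more than 5 (log2) brighter on the same array alone.

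The other 15 hypervariable genes spanned 1.40 to 2.71 on the log2 scale. Bst2, the interferon-induced tetherin, was at 3.01 on replicate 3 and between 0.34 and 0.47 on the others (adjusted p = 0.00107, limma). It too stood out on a single array, but the check for bright neighbours asked for more than 5 and did not cover it. The mean of the interferon list was lowest on replicate 3 (-0.06 from its own average). Chmp4bl1, a gene of the CHMP4B family, was at 1.95 on replicate 2 and between 3.86 and 4.13 on the others (adjusted p = 0.00375, limma); its second probe was at 0.07 on replicate 2 and between 1.74 and 1.99 on the others. The ribosomal RNA gene Rn5-8s was at 2.13, 1.07, 0.37 and 2.49 on replicates 1 to 4 (adjusted p = 0.00687, limma). The histone gene H1f4 was at 3.52, 2.86, 1.43 and 2.98 (adjusted p = 0.00827, limma), and the endoplasmic reticulum protein gene Retreg3 at 0.52, 1.38, 2.46 and 0.45 (adjusted p = 0.00827, limma). Pgd, Eml2, Tap2, Hnrnpa2b1, Shbg, Rn18s, Rn7sl1, Slc25a3, Gdf15 and Hira also passed, with adjusted p from 0.0149 to 0.0438. Retreg3, Pgd, Eml2, Tap2, Hnrnpa2b1, Gdf15 and Hira were each highest on replicate 3 and next on replicate 2. Rn5-8s, Rn18s, Rn7sl1 and H1f4 were each lowest on replicate 3 and next lowest on replicate 2. These genes share an order of the arrays, so their calls are not separate findings. Bst2, Chmp4bl1, Shbg and Slc25a3 followed neither order. Of these 15 genes, 0 were called by limma without trend or without replicate 3, and 2 with normexp or with cyclic loess; Rn7sl1 passed in 3 of 14 alternatives, and Slc25a3, Gdf15 and Hira in 4. The replicate 3 array was the most extreme for 12 of the 20 genes, replicate 4 for 5, replicate 1 for 2 and replicate 2 for 1. The count was 51, 63, 3 and 10 without replicates 1, 2, 3 and 4, and from 4 to 79 under the other alternatives fixed before the data were examined.

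**Figure D2:**
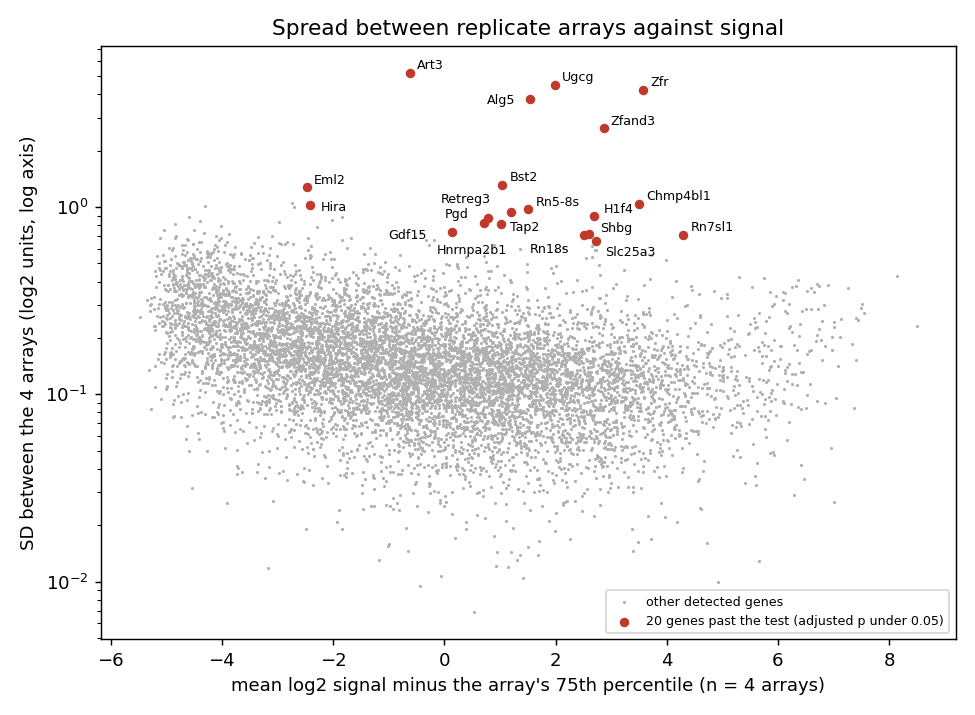
SD between the 4 arrays (y axis, log2 units on a log axis) against mean log2 signal relative to the 75th percentile (x axis); each point is a detected gene, and the 20 hypervariable genes are red and named. Art3, Ugcg, Zfr, Alg5 and Zfand3 lie at the top, far above the median SD of 0.144.

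**Figure D3:**
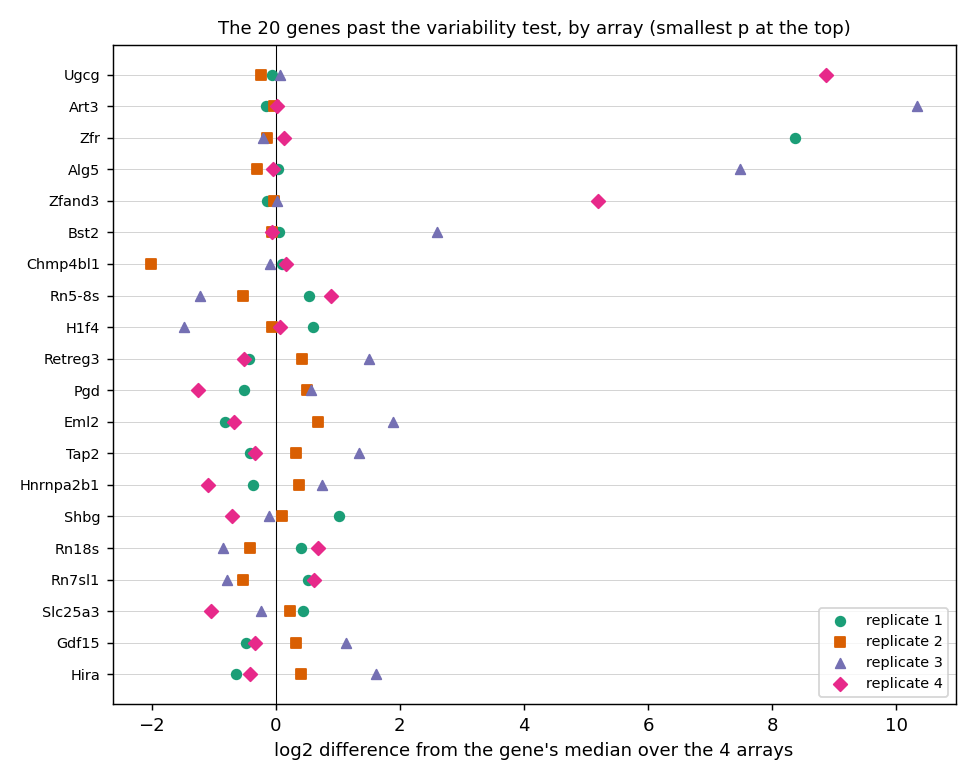
Log2 difference of each array from the median of the gene over the 4 arrays (x axis) for the 20 hypervariable genes (y axis, smallest p at the top), 1 symbol per replicate. For Ugcg, Art3, Zfr, Alg5 and Zfand3 a single array stands more than 5 above the others, and for Chmp4bl1 replicate 2 stands below.

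Among 19 lists with at least 5 detected members, 5 spread more than 95% of random lists of equal signal by at least 1 of the 2 measures, where chance gives about 0.95 per measure. By median SD, however, none of the 19 lists lay below percentile 50.2, the value of the phagocytic list. The lists as a class thus had a higher median SD than random lists, so the chance number is no fair yardstick for that measure. The metal response list passed percentile 95 by both measures, with a median SD of 0.267 against 0.136 in random lists (percentile 99.9) and an SD of the list mean of 0.17 against 0.06 (percentile 99.0). Within it Mt1 was at 3.75, 3.50, 3.99 and 4.71 and Mt2A at 0.34, 0.30, 0.91 and 1.53 on replicates 1 to 4, and 8 of the 9 members were above their own mean on replicate 4, while the mean of the 7 members other than Mt1 and Mt2A lay at percentile 67.4. Replicate 4 was also the array with the highest spot CV (9.60%, against 6.14% to 7.60%) and with 3 of 11 quality metrics out of range. The mean of the inflammatory cytokine list was 0.20 above its own average on replicate 3 and 0.10 below it on replicate 4 (percentile 98.7 of the SD of the list mean). Replicate 3 was also the array with the highest 75th percentile (1237, against 831 to 932), with 2 of 11 quality metrics out of range. Of its 15 members 11 were highest on replicate 3, such as Cxcl2 (1.36, against 0.39 to 0.88 on the others), and Ccl2, Ccl3 and Il18 were lowest there, Ccl2 at 5.29 against 5.66 to 5.93 and Ccl3 at 5.46 against 5.74 to 5.99. The members of the p53 list (percentile 97.2), the hypoxia list (96.9) and the cholesterol list (96.8) had a high median SD, while the SD of their list means was at percentiles 43.8, 43.2 and 90.7. The proliferation list (median SD percentile 62.4), the unfolded protein response list (56.1), the interferon list (68.5) and the macrophage list (78.2) lay below percentile 95 on it. The percentile of the list mean fell to 48.3 for the cytokine list without replicate 3 and to 94.2 for the metal list without replicate 4. It was 29.0 and 79.0 for these lists with no filter on dim probes, and 94.9 for the metal list with no scaling. The mean of the pattern recognition list lay at percentile 81.4 and passed 95 in 5 of 12 alternatives, all of them other scalings or background corrections (95.3 to 99.0), and that of the heat shock list lay at 92.6 and passed 95 in 4 of 12 (95.8 to 98.6).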

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

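The tests of bright areas, of structural RNAs of the Mt1 spots and of the metal response list without its metallothioneins, and the choice of cyclic loess, came after the results they bear on had been seen; the cut-offs for the loess test of the metal response list were set before it was run. A value was singled out when 1 of the 4 arrays lay far from the others by Dixon's test. Chance singles out about 1 in 20 groups of 4, and 12 of 131 sets of values were singled out. Of these, 7 were among the 20 hypervariable genes, which were included because their spread was high, and 5 among the other 111 sets, where chance gives about 5.55. By array these were 1, 3, 4 and 4 on replicates 1 to 4.

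Among lists, the mean of the macrophage list was higher on replicate 2 by 0.0936, and that of the phagocytic and scavenger receptors by 0.0852; these lists share 5 members, and the spread of their means lay at percentiles 38.3 and 36.6 of random lists. Among key genes, Hspa5 was lower on replicate 4 (-0.30), Nos2 higher on replicate 3 (0.42) and Pparg higher on replicate 4 (0.35), each against the median of the other arrays. Of the hypervariable genes, Bst2 was higher on replicate 3 (2.65) and Chmp4bl1 lower on replicate 2 (-2.10). The second Chmp4bl1 probe was also lowest on replicate 2, at 0.07.

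Art3 (10.37) and Alg5 (7.52) were far higher on replicate 3, Ugcg (8.93) and Zfand3 (5.22) on replicate 4, and Zfr (8.51) on replicate 1. Bright areas on the slide are a candidate explanation: 4 of these 5 genes had another spot within 3 rows and 3 columns that was also more than 5 brighter on that array alone, where the upper limit under random placement was 1. Over the 4 arrays 87 spots were that bright on 1 array alone, 72 with such a neighbour and 72 with an outlier flag, and 0 spots were as far below. Of the 87, 10 were control spots without a rat target, 6 of them with a bright neighbour. These included 2 of 2 on replicate 3 and 3 of 5 on replicate 4, the arrays of Art3, Alg5, Ugcg and Zfand3. On replicate 1 it was 0 of 2. Ugcg (row 108, column 54) and Zfand3 (row 109, column 52) were neighbours of each other, so they are not separate counts. A change of RNA gives no reason for bright spots to lie close together. The neighbours thus argue against it as the explanation for Art3, Alg5, Ugcg and Zfand3 as a set. Control spots do not measure these genes, and each gene had 1 named probe, so a change in any single gene is not excluded. Zfr had 0 bright neighbours and no second named probe, so for it bright areas and a change of its RNA cannot be told apart.

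The structural RNAs Rn5-8s, Rn18s, Rn45s and Rn7sl1, which carry no poly(A) tail or are precursors of such RNAs, spanned 1.27 in the mean of their 6 probes, lowest on replicate 3 and highest on replicate 4. The array scaling may contribute: without scaling the mean spanned 0.74, and with cyclic loess 1.11, so the smallest span lay between the limits set for and against that explanation and left it open. A differing uptake of RNA without a poly(A) tail into labelling might also account for it. Low values on replicate 3 were not particular to such RNA. The bright mRNAs Ftl1 (6.77, against 7.24 to 7.64 on the others) and Ctsd (6.17, against 6.65 to 7.04) were also lowest there. So were the bright mRNAs Lyz2, Gapdh, Txn1, Ctsb, Fth1, Ldha, Hspa8 and Krt79. Tyrobp and Fcgr2a, with lower means (5.77 and 5.90), were lowest on replicate 1. For Fcgr2a this was nearly a tie (5.83, against 5.85 on replicate 3). The 6 other replication-dependent histone genes (H1f5, H2ac21, H2ac25, H2ac4, H2bc12 and H4c14) had a list mean whose spread lay at percentile 98.0 of random lists, lowest on replicate 3 like the structural RNAs but highest on replicate 1, where the structural RNAs nearly tied (0.43 above their average, against 0.48 on replicate 4) and were highest without scaling, a setting in which the histones were highest on replicate 3, so the 2 explanations cannot be told apart. No biological explanation was tested, since the series holds 1 group.

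Of the 9 detected metal response genes, 8 were above their own mean on replicate 4 and 6 were highest there, Mt1 and Mt2A by the most, and without these 2, a choice that by construction lowers the spread, the list mean lay at percentile 67.4. That array had the smallest spike-in slope (0.840, against 0.911 to 0.927), the highest spot CV (9.60%, against 6.14% to 7.60%) and 3 of 11 quality metrics out of range (0, 1 and 2 on replicates 1 to 3). After cyclic loess, which removes trends with signal, the list mean stayed at percentile 99.0. The random lists were matched on mean signal, so such a trend moves them too and loess could hardly change the percentile. The loess result therefore cannot decide on a compressed signal range of that array. By the same matching, the list mean moved more than most random lists of equal signal, which was not seen without Mt1 and Mt2A. Defective spots are argued against for Mt1, since 10 of its 10 spots on replicate 4 were brighter than its brightest spot on any other array. A difference between the replicates may remain, as a hypothesis only; no biological explanation was tested, since the series holds 1 group.

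Some signal lay outside the analysed measurement. Of 96 ERCC control probes, 1 was well above background on 4 of 4 arrays, and 3.08% of ERCC spots were well above background against 5 of 1232 negative control spots. Of the 24489 probes without a gene name here, 6681 were well above background on 4 of 4 arrays and are not analysed here.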

How the results depend on the processing

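Cyclic loess and the removal of probes with a single far brighter array were chosen after the data were seen. The number of detected genes ranged from 8452 to 12150 under the alternatives run, against 8456. Leaving out 1 array gave 8478 to 8533, so the wide part of that range came from other detection rules. The number of lists past the detection test was 11 to 16, against 14. Both numbers lay within 1.5 times of the main one. Of the 34 lists, 22 kept their side of the threshold under all 8 alternatives, among them 8 of the 14 called, and 0 reversed. The hypervariable count of 20 fell to 10 with quantile normalization, with the 75th percentile over detected probes and at an adjusted p of 0.01. It fell to 7 with normexp on the median signal, which changed signal and background correction together, and with cyclic loess, to 4 without trend, to 9 without robust fitting and to 11 without the far brighter probes, and rose to 79 with no filter on dim probes. Leaving out 1 array gave 3 to 63 hypervariable genes, 127 to 226 genes over 2-fold and a median SD of 0.124 to 0.148. The range of a gene over fewer arrays cannot exceed its range over all of them, which lowers the count over 2-fold. Genes over 2-fold numbered 832 with no scaling, 3909 with no filter and 81 with normexp, against 275. The median SD moved from 0.144 to 0.267 with no scaling, 0.118 with normexp and 0.219 with no filter. The number of lists with a high spread was 8 with the 75th percentile over detected probes, against 5, and 4 to 7 when 1 array was left out. With no filter 16558 genes were tested, dim ones included; the cause of the other shifts was not tested. Without replicate 3, 3 of the 20 hypervariable genes were still called, and with quantile normalization 10. No paired analysis was possible because the series holds 1 group. The slide could not serve as a block, since all arrays share it. Signal near background limits what can be said of genes not detected, which were tested for variation only with no filter.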

Other observations

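The following gene families were chosen after the data were seen. Gene families that nearly every cell uses were detected almost in full in NR8383 cells. All 68 mitochondrial ribosomal protein genes and all 12 subunits of translation initiation factor 3 (Eif3) were detected. So were 37 of 38 proteasome subunits, 40 of 42 genes with the complex I prefix Nduf and 82 of 87 cytosolic ribosomal protein genes. Of the exceptions, the proteasome gene Psma8, the complex I gene Ndufs4 and the ribosomal protein gene Rps12l4 were partly detected. Ndufa4l2 and the ribosomal protein genes Rpl3l, Rpl27l2, Rpl39l5 and Rps4y2 were not detected. Over these 5 families 239 of 247 genes (96.8%) were detected.

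Families of sensory and structural genes gave the opposite picture. Of 1106 olfactory receptor genes, 23 (2.08%) were detected and 62 partly, and of 50 bitter taste and trace amine receptor genes only Taar5 was. Of 47 keratin genes, 4 were detected (Krt71, Krt79, Krt81 and Krt86); Krt79 is also a member of the alveolar macrophage list. Of 16 crystallin genes, Cryab, a small heat shock protein found in many tissues, and Cryga were detected.

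Among hypervariable genes with more than 1 named probe, the second probe of Tap2, a peptide transporter of antigen presentation, was at -0.94, -0.18, 0.75 and -0.67 on replicates 1 to 4, and the main one at 0.37, 1.11, 2.12 and 0.45. Both were thus highest on replicate 3. The second probe of Hira, a histone chaperone, stayed between -4.14 and -3.82, while the main probe ran from -3.29 to -1.04; both were highest on replicate 3.

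The 3 named probes of Rn45s, the ribosomal RNA precursor, were each lowest on replicate 3, at 5.96, 7.20 and 7.55, but 1 was highest on replicate 4 (7.61) and 2 on replicate 2 (8.14 and 8.55).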
